A study of Mus musculus with 6 samples.

How the data were processed

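RNA sequencing of mouse white adipose tissue gave 1 gene expression table for 6 samples, 3 control samples from mice given saline and 3 samples from mice given ginsenoside Rb1 at 14 mg/kg per day. Per the labels' protocols, total RNA was isolated with a column kit and libraries followed standard Illumina preparation. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.6 and the mouse genome build mm10. The counting tool, the annotation release, the strand setting and any filter on reads or genes are not given in the sources used here.

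The deposited table holds raw read counts per Ensembl gene, 1 column per sample, per the file headers, and the values are whole numbers with a different total in each column. It also holds FPKM values made by the authors, per the file headers. The deposited FPKM equalled the count divided by a gene length and by the column's total count. This was checked on the 13169 genes with at least 10 counts in all 6 samples, where the largest relative spread of the implied length was 0.00984%. Counts were used for every test and FPKM only to give levels. FPKM scales to the column total, so a library in which 1 tissue or a few genes take a larger share shows lower FPKM for all other genes. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. Of the genes named in the text, Ahr, Slc35a4, Lipe, Adrb3, Cpt1b, Fstl3, Prdm16, Ckmt2, Irs1, Cd22, Dusp1, Bhlhe40, Bhlhe41, Top2a, Ccna2, Ucp2, Serpina3k, Ckm, Mb, Myh1, Myh2, Itgad, Adnp, Fam13a, Stac, Pcdhgb7, Pla2g4e, Alpk2 and Stag2 share exon positions with another annotated gene, so their values are uncertain to that extent. How reads shared between near-identical genes were assigned is not given in the sources used here, so members of multigene families such as the haemoglobin genes are uncertain.

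Of 22040 gene identifiers, 21933 were paired with a symbol and 107 were not. Protein-coding genes made up 21851 of them, and 4569 genes had 0 counts in all 6 samples. Coordinates and gene types came from GENCODE M21 on GRCm38, the assembly that mm10 denotes. That release may differ from the one the authors counted with.

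Total counts per sample ranged from 15440339 to 24501446. A count of 0 allows a level of up to 3 counts, which is 0.122 to 0.194 CPM, the count scaled by the library total, at these depths. Shares of counts in single samples carry exact Clopper-Pearson 95% intervals. Reads carry no molecular identifiers here, so intervals and floors cover counting error only. The labels do not say that the replicates of a group came from separate mice, so p-values measure the spread between these samples, which may be partly technical. No pair of samples agreed within sampling noise, since the chi-square per degree of freedom over genes was at least 31.78 for every pair, and all 6 were used as separate samples.

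The main test was edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default expression filter (a minimum count of 10 and a minimum total of 15), and the quasi-likelihood test of Rb1 against control with no covariates. It was run on 14093 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.0616, a biological coefficient of variation of 24.8%. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. The 35 gene lists, fixed before the data were examined, covered adipocyte and metabolic pathways, stress responses, immune and stromal cell types, and other tissues that a fat sample can carry. The 32 lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it. For each list, genes were also counted with the p-value adjusted over the list alone. Single values were tested with an exact two-sided permutation test, whose smallest possible p with 3 samples against 3 is 0.1.

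The genes named were chosen by a rule fixed before the data were examined. It took Mstn, up to 12 genes with the largest rise and up to 12 with the largest fall among those past the threshold with non-overlapping groups and a mean of at least 1 CPM, and up to 4 members of each list with the smallest p. A fixed set of 11 genes of adipose biology was added. Where fewer than 5 genes passed in a direction, the 5 with the smallest unadjusted p in that direction were taken and are reported as not passing. Unnamed predicted genes and pseudogenes were skipped, and a few genes that the rule takes are not reported here.

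Counts were simulated from the means and edgeR dispersions of the tested genes, and 13966 of the simulated genes were run. Of these, 100 were changed 2-fold and 100 were changed 4-fold, all drawn from genes with a mean of at least 1 CPM. On these counts edgeR recovered 32% of 2-fold and 94% of 4-fold changes, with 13 false calls among 139. DESeq2 1.42.0 recovered 59% and 99%, with 62 false calls among 220. Limma-voom recovered 32% and 93%, with 12 false calls among 137. On simulated lists of 20 genes shifted by 0.5 log2, camera called 25 of 25 with the preset correlation and 24 of 25 with an estimated correlation, and 0 of 75 unshifted lists with either. The simulated genes varied independently of each other. In the real lists the estimated correlation ran from -0.07 (neutrophil) to 0.81 (mitochondrially encoded genes), with 0.20 for macrophage and 0.47 for cell cycle genes. The simulation therefore does not show how either version of camera performs on lists of correlated genes.

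Alternatives fixed before the data were examined were DESeq2, limma-voom, DESeq2-type size factors within edgeR, no expression filter, a mean of at least 1 CPM, an absolute log2 fold change of at least 1, the replicate number as a block, and leaving out each sample in turn. Robust edgeR and DESeq2 without control replicate 2 were added after the data were seen. Settings planned for a table of normalized values alone, such as other pseudocounts, were not run because the table holds counts.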

Results

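Gene expression in mouse white adipose tissue was measured by RNA sequencing in 3 control samples, from mice injected intraperitoneally with saline, and in 3 samples from mice injected with ginsenoside Rb1, a triterpene saponin of ginseng, at 14 mg/kg per day. The series title ties the work to myostatin and to the anti-obesity action of Rb1, so the comparison asks which transcripts of the tissue differ after Rb1 and whether Mstn, the myostatin gene, is among them. Fat depot, diet, strain and length of treatment are not given in the sources used here. Total counts were 19125095, 23509621 and 20179431 in control replicates 1, 2 and 3, and 20226859, 15440339 and 24501446 in Rb1 replicates 1, 2 and 3. The 10 most abundant genes took 11.18% to 15.78% of the counts, and Scd1, a fatty acid desaturase, took 2.08% to 6.67% alone. Pearson correlations of log2 values across genes lay between 0.93 and 0.979 for all pairs of samples.

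Control replicate 2 stood apart from the other 5 samples through transcripts of skeletal muscle. Muscle genes of the list fixed beforehand took 3.74% of its counts (exact 95% interval 3.73 to 3.75), against 0.0575% and 0.0583% in control replicates 1 and 3 and 0.0270%, 0.00762% and 0.0132% in the Rb1 replicates. Myh4, a fast myosin heavy chain, had 314218 counts in control replicate 2 and between 174 and 2832 in the other 5. Of 22 tested muscle genes, 20 were highest in that library, and the median ratio over the 22 to the mean of the other controls was 49.2. On the principal component that held 57.0% of the variance it scored -58.0, and the other samples scored between -7.3 and 33.8. The muscle list was lower in Rb1 by a median log2 fold change of -6.20 with all samples (camera adjusted p = 2.53e-10, and adjusted p = 0.512 with an estimated correlation). The median was -2.10 without control replicate 2. No muscle gene of the list passed over all genes, and 20 of 22 were lower when adjusted over the list alone, or 19 of 22 without control replicate 2.

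Mstn, which encodes the secreted inhibitor of muscle growth, was detected in all 3 controls and hardly at all after Rb1, and most of its reads came from the library rich in muscle transcripts. Its counts were 18, 325 and 10 in control replicates 1, 2 and 3 and 0, 0 and 1 in Rb1 replicates 1, 2 and 3. These correspond to 0.941, 13.8 and 0.496 CPM (the count scaled by the library total) in the controls. In the Rb1 group they correspond to at most 0.148 and 0.194 CPM in the 2 libraries without a read, and to 0.0408 CPM in the library with 1 read. The gene (ENSMUSG00000026100) lies on chromosome 1 from 53061640 to 53068079 on the plus strand and shares exons with no other annotated gene. In FPKM, the level was 0.985 ± 1.47 in controls and 0.00263 ± 0.00456 with Rb1 (SD, n = 3 each). Pooled over libraries, the level in controls was 338 times that with Rb1, with a counting interval of 60.3 to 13400, on 353 against 1 counts. Leaving out control replicate 2 gave a ratio of 42.9, with an interval of 7.09 to 1750, on 28 against 1 counts. The 3 control values all lay above the 3 Rb1 values, which gave an exact permutation p of 0.1, the smallest that 3 samples against 3 allow. In edgeR the difference did not pass (log2 fold change -7.80, SE 2.01, adjusted p = 0.251). Without control replicate 2 it was -4.94 with adjusted p = 0.289, and both fitted values depend on the prior count because the Rb1 group is close to 0.

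**Figure D1:**
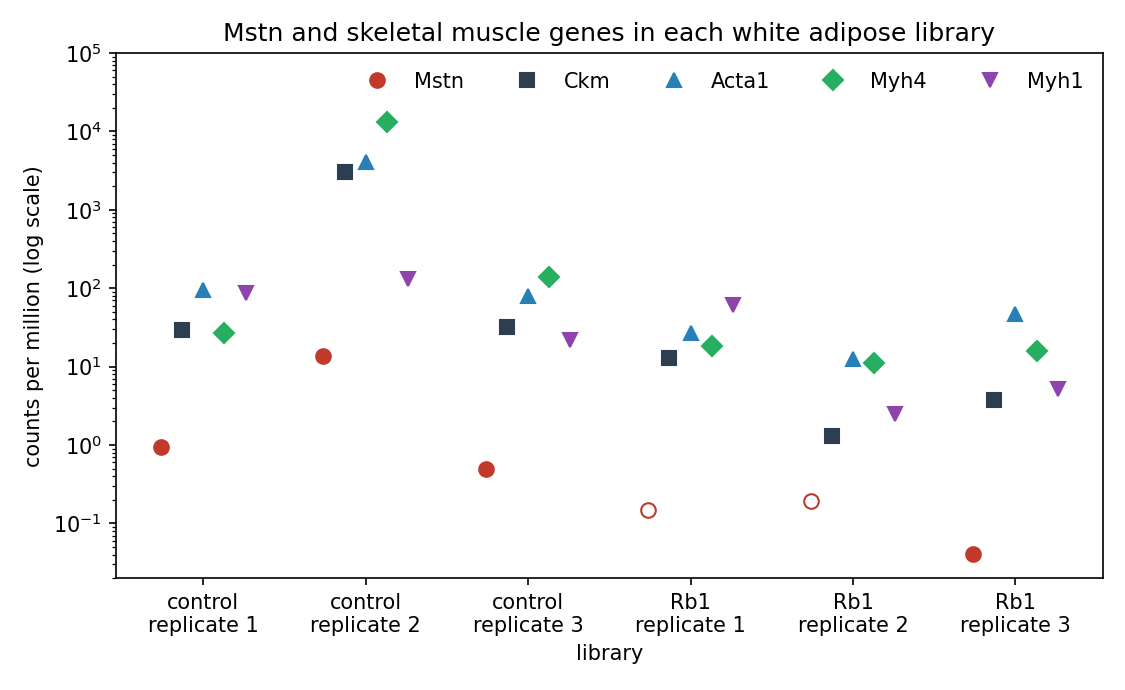
CPM on a log axis for Mstn and 4 skeletal muscle genes (Ckm, Acta1, Myh4, Myh1) in each of the 6 libraries, 1 symbol per library. Open circles mark the limit that 0 counts of Mstn allow, which is 3 counts of the total. All 5 genes were highest in control replicate 2, where Mstn reached 13.8 CPM.

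Xiap, which encodes an inhibitor of caspases, was the 1 gene past the threshold and rose 4.98-fold with Rb1. It went from 3.02 ± 0.107 to 14.6 ± 1.36 FPKM (SD, n = 3 each), a log2 fold change of 2.32 with an SE of 0.09 and an edgeR adjusted p of 0.0007996. The gene (ENSMUSG00000025860) lies on chromosome X from 42059679 to 42109656 on the plus strand, with no exon shared with another gene, and the call held without each library in turn. A jump of similar size across libraries of both groups was seen for Tlr4, at 0.946 to 1.03 FPKM in 3 libraries and 5.57 to 7.07 in the other 3. No gene fell past the threshold in edgeR. At an unadjusted p under 0.05 there were 565 genes higher and 1063 lower, against 705 in all by chance and 1313 in the highest of the 9 other splits of the samples into 3 and 3. Those splits mix the groups unevenly and so carry part of any group difference. DESeq2 called 83 higher and 307 lower. Control and Rb1 values did not overlap for 17.5% of genes, against 10% by chance. After leaving out control replicate 2, edgeR had 1183 genes at an unadjusted p under 0.05 and DESeq2 called 35 higher and 161 lower. Leaving out Rb1 replicate 1, 2 or 3 changed the edgeR count from 1 to 3, 4 or 2.

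Among genes with non-overlapping groups, those with the smallest p after Xiap did not pass over all genes in edgeR. On the higher side were Grhl1, an epithelial transcription factor (log2 fold change 1.27, adjusted p = 0.120), and Hsd11b1, which regenerates active glucocorticoid in fat (0.93, adjusted p = 0.127). Hsd11b1 stood at 9.98 ± 0.732 FPKM in controls and 18.6 ± 3.15 with Rb1 (SD, n = 3 each). Slc25a42, a mitochondrial carrier of coenzyme A, was higher by 0.75 (adjusted p = 0.128), as was Ahr, the aryl hydrocarbon receptor (0.75, adjusted p = 0.155), whose exons overlap the predicted gene Gm48236. On the lower side were Itgax, the macrophage and dendritic cell integrin CD11c (-1.55, adjusted p = 0.0744), and Atf3, a stress-induced transcription factor (-1.45, adjusted p = 0.0744). Itgax went from 14.1 ± 2.88 to 4.63 ± 0.496 FPKM and Atf3 from 13.3 ± 1.83 to 4.74 ± 0.724. Myo1f, a myosin of leukocytes (-1.18), and Slc35a4 (-1.12), whose exons overlap Apbb3, each had an adjusted p of 0.0764. DESeq2 called each of these genes, with adjusted p of at most 0.0003832 (Ahr). On GRCm38, Grhl1 lies on chromosome 12 from 24572283 to 24617391, Hsd11b1 on chromosome 1 from 193221634 to 193264075 and Slc25a42 on chromosome 8 from 70184340 to 70212305. Itgax lies on chromosome 7 from 128129547 to 128150657 and Atf3 on chromosome 1 from 191170296 to 191218039. Ahr lies on chromosome 12 from 35497974 to 35535038, Slc35a4 on chromosome 18 from 36679215 to 36683861 and Myo1f on chromosome 17 from 33555707 to 33607764.

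Macrophage genes were lower with Rb1 as a group. Of 20 tested macrophage genes 18 had negative values, with a median log2 fold change of -0.75 (camera adjusted p = 5.13e-10, and adjusted p = 0.447 with an estimated correlation). Those with the smallest p were Itgax, Atp6v0d2, a proton pump subunit of phagocytes (-1.52), Trem2, a lipid-sensing receptor (-1.42), and Gpnmb, a glycoprotein of lipid-laden macrophages (-0.88). Trem2 stood at 7.10 ± 2.49 FPKM in controls and 2.55 ± 0.404 with Rb1 (SD, n = 3 each). Adgre1, which encodes F4/80, stood at 33.5 ± 7.54 and 17.9 ± 4.27 (-0.86, edgeR adjusted p = 0.286, DESeq2 adjusted p = 0.0413). Values near 0 were those of Clec10a (0.01), Cd209f (-0.05) and Mrc1 (-0.18), and Cd163 was at 0.23. None of the 20 passed over all genes in edgeR, 9 were lower in DESeq2, and 10 were lower when adjusted over the list alone. Without control replicate 2 the median was -0.64 and 8 were lower over the list alone, and without Rb1 replicate 1 the median was -0.49.

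Genes of other immune functions were lower too, with less support per gene. The 19 inflammatory cytokines and chemokines had a median of -0.73, 18 of them negative (camera adjusted p = 5.12e-05, and adjusted p = 0.512 with an estimated correlation). Its leading member Ccl4, a macrophage chemokine, stood at 1.69 ± 0.513 FPKM in controls and 0.553 ± 0.105 with Rb1 (SD, n = 3 each, log2 fold change -1.56). Type I interferon response genes had a median of -0.28 with 17 of 20 negative (camera adjusted p = 0.000843, and adjusted p = 0.512 with an estimated correlation), among them Mx1 (-1.32) and Stat2 (-0.47). The T and NK cell list had a median of -0.70 over 16 genes (camera adjusted p = 0.00239, and adjusted p = 0.675 with an estimated correlation), led by Cd8b1 (-1.35). The B cell list had a median of -0.45 over 11 genes, 8 of them negative (camera adjusted p = 0.0031, and adjusted p = 0.512 with an estimated correlation). It was led by the adaptor Blnk (-1.09) and Cd22 (-1.30). Cd22 was at a low level, 0.404 ± 0.140 FPKM in controls and 0.158 ± 0.0496 with Rb1. Adjusted over the list alone, Blnk and Cd22 were lower (Blnk alone without control replicate 2) and no gene of the cytokine, interferon or T and NK lists was, while over all genes edgeR called none of the 4 lists' members. Without control replicate 2, the library with most muscle transcripts, the T and NK cell median was -0.38 (camera adjusted p = 0.0983) and the B cell median -0.11 (camera adjusted p = 0.248). The T and NK call was also lost without Rb1 replicate 2 (adjusted p = 0.0765), and the B cell call without control replicate 1 (0.167), Rb1 replicate 2 (0.0538) or Rb1 replicate 3 (0.163) and with no expression filter (0.247). Without Rb1 replicate 1 the medians were -1.37 for cytokines, -1.24 for T and NK cells and -0.89 for B cells. The cytokine median was closest to 0 without Rb1 replicate 3 (-0.61). The 5 tested neutrophil genes were not called (median -0.07, and -0.38 to 0.61 when 1 library was left out, camera adjusted p = 0.747). Mmp9 alone was higher when adjusted over the list alone, and no neutrophil gene was without control replicate 2.

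Cell cycle genes were lower with Rb1 as a group. All 22 had negative log2 fold changes and 19 had non-overlapping groups, with a median of -0.87 (camera adjusted p = 4.25e-17, and adjusted p = 0.447 with an estimated correlation). Mki67, the proliferation marker Ki-67, stood at 4.74 ± 0.635 FPKM in controls and 2.15 ± 0.323 with Rb1 (SD, n = 3 each, log2 fold change -1.09, edgeR adjusted p = 0.119). Top2a, the DNA topoisomerase of dividing cells (-0.89), the cyclin Ccna2 (-1.08) and the mitotic kinase Aurka (-1.01) were lower by similar amounts, all at low levels of under 2 FPKM in controls. None passed over all genes in edgeR, 7 were lower in DESeq2, and 16 of 22 were lower when adjusted over the list alone. Without control replicate 2 the median was -0.77, and 2 of 22 (Mki67 and Top2a) were lower over the list alone.

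**Figure D2:**
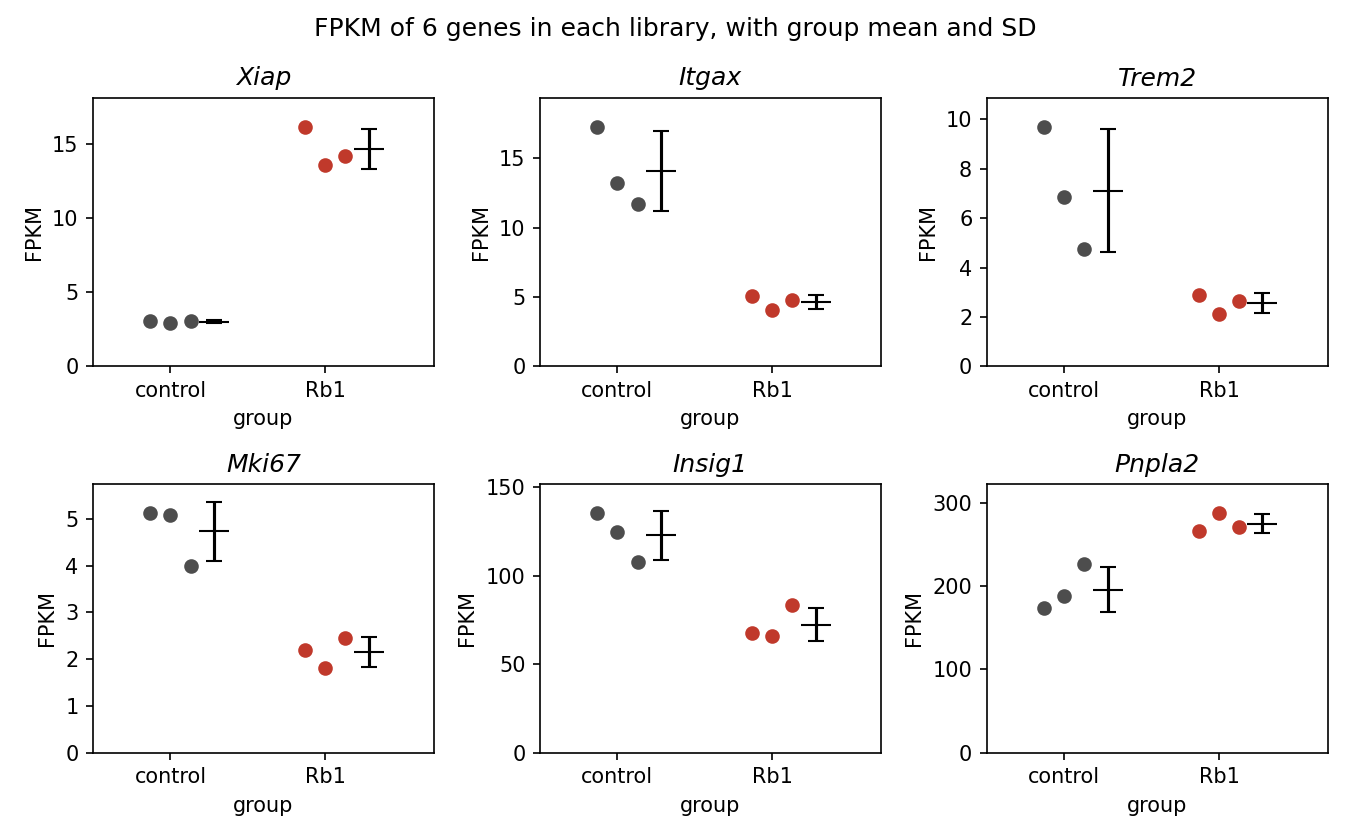
FPKM of Xiap, Itgax, Trem2, Mki67, Insig1 and Pnpla2 in each library of the control and Rb1 groups, with the group mean and SD (n = 3) drawn to the right of the points. The groups do not overlap for any of the 6 genes, and Xiap alone passed the threshold over all genes in edgeR.

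Cholesterol synthesis genes and immediate early and heat shock genes were lower as groups. Of 19 tested genes of the cholesterol synthesis list 18 had negative values, with a median of -0.33 (camera adjusted p = 1.7e-05, and adjusted p = 0.512 with an estimated correlation). Insig1, which retains the sterol sensor in the endoplasmic reticulum, went from 123 ± 13.9 to 72.2 ± 9.43 FPKM (SD, n = 3 each, log2 fold change -0.71), and Hsd17b7, an enzyme of the pathway, had a log2 fold change of -0.49. Adjusted over the list alone, 2 genes were lower, Insig1 among them, and no gene passed over all genes, and without control replicate 2 the count over the list alone was 4. The median was -0.52 without Rb1 replicate 3 and -0.28 without Rb1 replicate 1. The immediate early and heat shock list, which reflects tissue handling as well as stimulation, had a median of -0.47 over 18 genes (camera adjusted p = 0.000823, and adjusted p = 0.512 with an estimated correlation). Its lower members over the list alone were Atf3 and Dusp1, a MAP kinase phosphatase (-0.84), and none passed over all genes.

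Genes of lipid breakdown were slightly higher with Rb1 as groups. Lipolysis genes had a median of 0.26 over 15 genes, 12 of them positive (camera adjusted p = 0.00313, and adjusted p = 0.512 with an estimated correlation). Pnpla2, the triglyceride lipase ATGL, stood at 196 ± 27.3 FPKM in controls and 275 ± 11.4 with Rb1 (SD, n = 3 each, log2 fold change 0.53, edgeR adjusted p = 0.309). Lipe, hormone-sensitive lipase (0.40), Pde3b, an antilipolytic phosphodiesterase (0.54), and Aqp7, the glycerol channel (0.66), were on the same side. With an antilipolytic member among the higher genes, the list has no single functional direction. Aqp7, Adrb3, Plin1 and Fabp4 are also on the mature adipocyte list, so the 2 lists are not independent. Fatty acid oxidation genes had a median of 0.19 with 21 of 24 positive (camera adjusted p = 0.00239, and adjusted p = 0.659 with an estimated correlation), led by Acads (0.33) and Acaa2 (0.34). Insulin signalling genes had a median of 0.14 over 20 genes (camera adjusted p = 0.0273, and adjusted p = 0.659 with an estimated correlation), with Irs1 at 0.60 and Socs3 at -0.49. No gene of these 3 lists passed over all genes or when adjusted over the list alone, although the insulin signalling gene Tbc1d4 was higher over the list alone without control replicate 2. The lipolysis median was 0.15 without Rb1 replicate 1 and the oxidation median 0.09 without Rb1 replicate 3. The insulin median ran from 0.10 without control replicate 1 to 0.27 without control replicate 3. Without Rb1 replicate 3 the lipolysis and oxidation calls were lost (camera adjusted p = 0.0507 and 0.173), and the insulin call was lost without control replicate 1 (0.213), control replicate 2 (0.0572) or Rb1 replicate 2 (0.108).

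The remaining adipocyte lists were not called, and 0 of their genes passed when adjusted over the list alone or over all genes in edgeR. Median log2 fold changes were 0.15 for mature adipocyte genes (camera adjusted p = 0.142), 0.09 for lipogenesis and triglyceride synthesis (0.659), 0.01 for adipogenic regulators (0.827) and 0.00 for adipokines (0.666). Oxidative phosphorylation genes had a median of 0.07 (0.255) and the mitochondrially encoded genes -0.01 (0.883). Leaving out 1 library brought 3 of these lists past the threshold, all higher. Lipogenesis passed without Rb1 replicate 1 (median 0.28, camera adjusted p = 0.0001208), mature adipocyte genes without Rb1 replicate 1 (0.01023) or control replicate 3 (0.03923), and oxidative phosphorylation without control replicate 2 (0.02268) or Rb1 replicate 2 (0.01341). Adiponectin (Adipoq) was at 1595 ± 79.8 FPKM in controls and 1390 ± 118 with Rb1 (SD, n = 3 each, log2 fold change -0.16, edgeR adjusted p = 0.729). Other fixed genes were Lep (-0.33), Pparg (-0.10), Fasn (0.52), Scd1 (0.43) and Ppargc1a (0.06), with adjusted p between 0.631 and 0.968. Leaving out 1 library moved Lep between -0.49 and -0.17, Pparg between -0.18 and 0.00, Fasn between 0.12 and 0.95, Scd1 between 0.09 and 0.80 and Ppargc1a between -0.11 and 0.33. The thermogenic and beige list had a median of -0.47 (camera adjusted p = 0.234) that was 0.05 without control replicate 2. It contains Ckmt2 (-7.03, and -3.83 without control replicate 2) and Cpt1b (-1.08, and -0.16), which skeletal muscle also expresses and which were highest in control replicate 2. Ucp1, the uncoupling protein of brown fat, ranged from 0 to 4.37 FPKM in controls and from 0 to 1.87 with Rb1. Its log2 fold change was -1.25 (adjusted p = 0.807), and 0.37 without control replicate 2. Prdm16, a regulator of beige fat, stood at 2.02 ± 0.0887 in controls and 2.69 ± 0.135 with Rb1 (log2 fold change 0.45, edgeR adjusted p = 0.216, DESeq2 adjusted p = 0.0296).

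Myostatin and activin signalling genes were lower by a median of -0.25 over 20 genes, 16 of them negative (camera adjusted p = 0.00349, and adjusted p = 0.447 with an estimated correlation). After Mstn, the members with the smallest p were the receptor Tgfbr1 (-0.32), the activin antagonist Fstl3 (-0.49) and the activin subunit Inhbb (-0.38). With an antagonist among the lower genes, the list has no single functional direction. Mstn itself is a member, and the list was not tested without it. Inhbb stood at 26.9 ± 1.77 FPKM in controls and 20.1 ± 3.54 with Rb1 (SD, n = 3 each). None passed over all genes or when adjusted over the list alone, and without control replicate 2 the median was -0.17 and 2 genes (Mstn and Fstl3) were lower over the list alone.

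Vascular and blood genes were higher with Rb1 as groups. All 18 endothelial genes had positive values, with a median of 0.29 (camera adjusted p = 0.000295, and adjusted p = 0.574 with an estimated correlation), led by Flt1, a VEGF receptor (0.60), and Tek, the angiopoietin receptor (0.38). Flt1 stood at 13.1 ± 0.851 FPKM in controls and 19.4 ± 4.41 with Rb1 (SD, n = 3 each), and without Rb1 replicate 1 the median of the list was 0.13. Erythroid and blood genes had a median of 0.63 over 10 genes (camera adjusted p = 0.00812, and adjusted p = 0.512 with an estimated correlation), led by the haemoglobin gene Hba-a1 (0.87), and the call was lost without Rb1 replicate 3 (median 0.37, camera adjusted p = 0.0875). No gene of either list passed over all genes or when adjusted over the list alone. Other cell type and tissue lists were not called with all samples. Their medians were 0.14 for adipose progenitors and fibroblasts (camera adjusted p = 0.142), 0.13 for smooth muscle and pericytes (0.374), 0.24 for mesothelium (0.114), -0.03 for liver (0.727) and 0.07 for extracellular matrix (0.827). Adjusted over the list alone, Cldn15 of the mesothelial list was higher and no gene of the other 4, and without control replicate 2 no mesothelial gene was. The extracellular matrix and progenitor lists passed as higher without Rb1 replicate 1 (medians 0.31 and 0.26, camera adjusted p = 0.0005516 and 0.002152), and the mesothelial list without control replicate 3 (0.59, 0.00608).

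**Figure D3:**
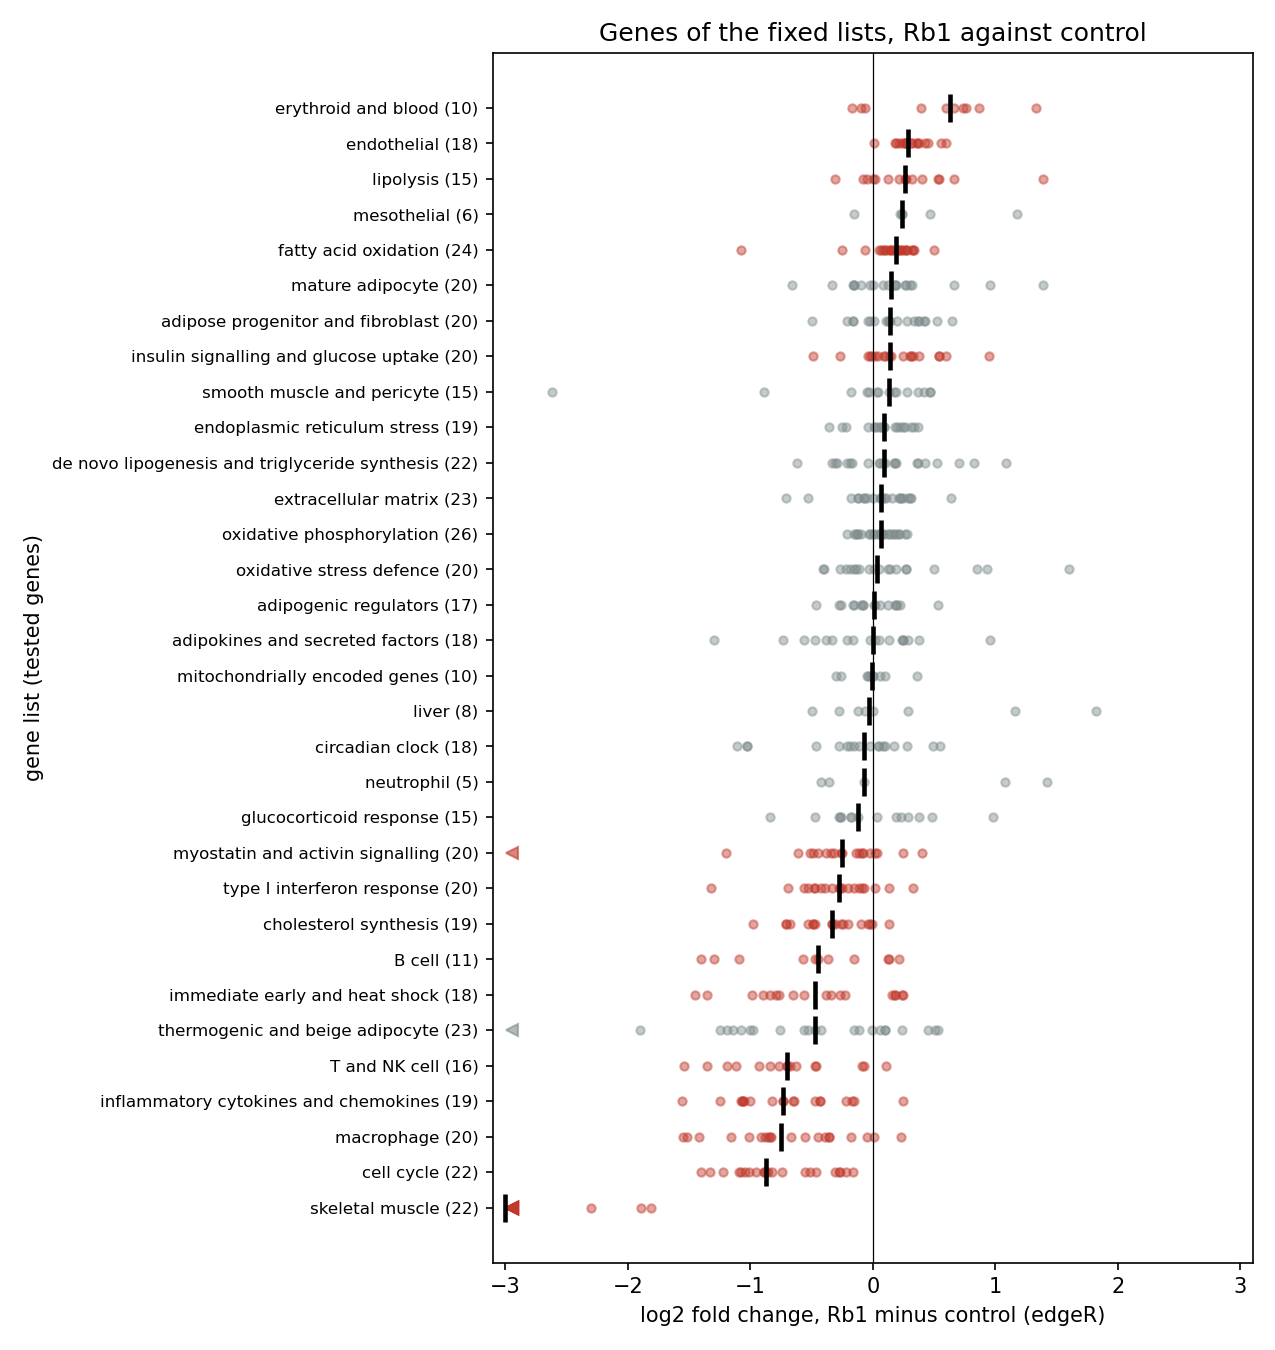
Log2 fold changes (edgeR, Rb1 minus control) of the genes in each of the 32 tested lists, 1 point per gene, with the list median as a black bar and the number of tested genes in parentheses. Red lists passed camera with the preset correlation, 15 of 32, and 0 of 32 passed with an estimated correlation. Triangles at the left edge, and the bar of the muscle list there, stand for values below -3.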

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

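Robust edgeR and DESeq2 without control replicate 2 were chosen after the data were seen, and all other alternatives were planned. The count of changed genes stayed at 1 (Xiap, higher) under limma-voom, other size factors, no expression filter, a mean of at least 1 CPM, a log2 fold change of at least 1 and robust edgeR. DESeq2 called 390 genes, 83 higher and 307 lower, and without control replicate 2 it called 196, 35 higher and 161 lower. Of the 390, 389 had an edgeR unadjusted p under 0.05. On simulated counts 62 of 220 DESeq2 calls were false, against 13 of 139 for edgeR. The simulation used edgeR dispersions and a fixed number of changed genes, so these shares do not give the share of false calls among the 390. Leaving out 1 library gave 1 to 4 changed genes in edgeR, 1 to 2 higher and 0 to 2 lower, with Xiap called each time at a log2 fold change of 2.29 to 2.35. Of the 32 gene lists, 15 passed camera with a preset correlation, 0 with an estimated correlation and 0 with fry in place of camera, and 11 to 19 passed when 1 library was left out. No filter and a mean of at least 1 CPM each gave 14 lists, and other size factors gave 15. The Mstn difference stayed negative and short of the threshold under every alternative with an adjusted p, with log2 fold changes from -9.66 to -4.94 and adjusted p from 0.151 to 0.576. DESeq2 gave Mstn no adjusted p. The replicate numbers gave no sign of pairing, since deviations of same-numbered samples correlated at 0.14, -0.11 and 0.02. Those of differently numbered samples ran from -0.26 to 0.26. Such weak correlations cannot exclude a pairing. The replicate block gave 1 gene, 16 lists and an Mstn log2 fold change of -7.22 (adjusted p = 0.223). Directions reversed for 7 of the named genes when 1 library was left out, none of them past the threshold. Their log2 fold changes ranged from -2.75 to 0.37 for Ucp1 (0.34 in DESeq2 without control replicate 2), -0.11 to 0.33 for Ppargc1a and -1.36 to 0.12 for S100a8. They ranged from -0.12 to 0.81 for Gpm6a, -0.16 to 0.59 for Rspo1, -0.03 to 0.21 for mt-Cytb and -0.08 to 0.68 for Serpina3k. For Ucp1 the reversal came with the loss of the library holding 4.37 FPKM, and for the others the cause was not tested. Depth limits Mstn, since 0 counts allow up to 0.194 CPM.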

Other observations

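The gene lists and the leave-one-out values were planned. The counts over other splits of the samples, and the search of those splits for genes that jump between libraries, had their predictions written before they were run. The other tests of explanations for Mstn, the macrophage genes and Xiap, and the naming of DESeq2 genes, were chosen after the results were seen. The macrophage subset lists were chosen after several of their genes had been seen, and the test on the resident list replaced an earlier comparison of both lists.

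Some genes were called in DESeq2 and not in edgeR. The same naming rule applied to the DESeq2 calls, a choice made afterwards, gave on the higher side, among others such as Ncam2, Alb, Adnp, Pcdhgb7, Chrna5 and Stac, Gpx3, a secreted glutathione peroxidase, at 67.1 ± 10.7 FPKM in controls and 198 ± 105 with Rb1 (SD, n = 3 each, DESeq2 adjusted p = 0.003954, edgeR adjusted p = 0.2575). Cyp26b1, which degrades retinoic acid, stood at 1.58 ± 0.513 and 4.53 ± 0.726 (DESeq2 adjusted p = 1.776e-05, edgeR adjusted p = 0.1668), and Fam13a at 6.08 ± 2.45 and 16.5 ± 4.97 (0.001868 and 0.2293). On the lower side Itgad, a leukocyte integrin, stood at 13.6 ± 3.87 and 3.08 ± 1.60, and Rgs1, a regulator of chemokine signalling, at 0.968 ± 0.556 and 0.190 ± 0.0598 (DESeq2 adjusted p = 0.0003832 and 1.759e-05). Among the genes named from the DESeq2 calls, Ckmt2, Smtnl1, Pla2g4e, Alpk2 and Kcnc1 had the largest falls. All 5 were highest in control replicate 2, the library with most muscle transcripts.

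Stress and clock lists were not called with all samples. Oxidative stress genes had a median of 0.03 over 20 genes (camera adjusted p = 0.827), with Gpx3 (1.60) and Gsta3 (0.93) higher and the mitochondrial carrier Ucp2 (-0.41) lower when adjusted over the list alone. Clock genes had a median of -0.07 over 18 genes (camera adjusted p = 0.47), and Bhlhe40 (-1.11) and Bhlhe41 (-1.03), paired repressors of the clock, were lower over the list alone. Glucocorticoid response genes had a median of -0.12 (0.827), with Dusp1 lower over the list alone, and endoplasmic reticulum stress genes 0.09 (0.139, and 0.0361 without control replicate 3), with none. With control replicate 2 left out, no oxidative stress or clock gene passed over the list alone, and Dusp1 was lower over the glucocorticoid response list. Over all genes edgeR called no member of these 4 lists. The lists for mammary and skin epithelium, pancreas, and epididymis and testis had 3, 2 and 0 tested genes and were not tested as groups.

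Mstn was higher in controls, and 325 of its 353 control reads came from control replicate 2. Muscle carried into that sample may account for its Mstn, since 20 of 22 tested muscle genes were highest there, with Myh4 at 314218, Acta1 at 97128 and Ckm at 71700 counts. Whether muscle RNA alone sets the Mstn counts of control replicates 1 and 3 cannot be told apart from other sources. Scaling control replicate 2 by each muscle gene predicted a median of 11.2 counts in both together, against 28 observed, and 3 of 22 genes (Myh1, Myh2 and Mb) predicted more than 28 and set the 95th percentile of 681, while in the Rb1 libraries the median was 4.04 against 1 observed. A lower Mstn level in adipose cells themselves stays open too. Without control replicate 2 the edgeR adjusted p of Mstn was 0.289 over all genes and 0.0243 over its list alone, and muscle transcripts were also lower with Rb1. The other alternatives with an adjusted p over all genes, from 0.151 to 0.576, all kept control replicate 2.

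Macrophage genes were lower, with Trem2, Gpnmb, Itgax and Atp6v0d2 in front. Control replicate 2 alone does not account for it, because the list's median was -0.64 without that library. More adipocyte RNA diluting all other cells would also lower endothelial genes, whose median was 0.29. A lower share of macrophages of every kind would lower resident perivascular markers as well. Those markers had a median of 0.07 over 16 genes, 7 of them negative (bootstrap 95% interval over genes -0.18 to 0.25, and -0.16 to 0.18 without 1 library). The 12 that are not on the macrophage list had a median of 0.16 (-0.32 to 0.30) with 5 negative, although Lyve1 among them is also an endothelial gene. Bootstrap intervals over genes treat the genes as independent and do not cover the spread between samples. They therefore cannot exclude a smaller fall of the resident markers. Fewer or less active lipid-associated macrophages with Rb1 stays open as a hypothesis found on these same samples, since 5 of its 18 markers are macrophage list genes that prompted it, and the other 13 had a median of -0.24 with 10 negative (bootstrap 95% interval over genes -0.55 to -0.10). Cd36 (0.18), among those 13, is also on the mature adipocyte list.

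Xiap was 4.98-fold higher with Rb1, with a gap of 2.17 log2 between groups and ranges of 0.12 and 0.13 log2 within them. Reads from the tested genes within 500 kb do not account for it, since the largest log2 fold change among them was 0.22 (Stag2). Reads from genes that were not tested, or from similar sequences elsewhere in the genome, could not be examined this way. Counts of some genes may jump between libraries whatever their group, since 1 of the other 9 splits of the libraries also held a gene with a gap over 2 log2 and ranges under 0.5 log2. That gene was Tlr4, a receptor for bacterial lipopolysaccharide, at 0.946 to 1.03 FPKM in control replicates 1 and 3 and Rb1 replicate 1 and at 5.57 to 7.07 in the other 3 libraries. A genotype or cage difference between the groups cannot be told apart from an Rb1 effect, since the labels give neither, and 4 other genes (Itgax, Atf3, Dhrs9 and St18) had a gap over 1 log2 between the groups and ranges under 0.5 log2 within them, 5 with Xiap, against 6 in the split that held Tlr4.

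The 6 samples allow 10 splits of 3 against 3, too few for a share under 0.05. In edgeR 3 of the 10 gave at least 1 gene, where the real groups gave 1 and the highest other split 2. For the gene lists 3 of the 10 gave at least 15, where the highest other split gave 17. With DESeq2 the real groups gave 390 genes and the highest other split 196, so 1 split of 10 gave as many. The smallest camera p (preset correlation) of the macrophage list over other splits was 1.53e-05, against 4.81e-11 for the real groups, and that of the cell cycle list was 4.85e-08 against 1.33e-18. Both lists were among those with the smallest camera p in the real groups, so the smaller p there is partly set by that choice. A p as small as 4.85e-08 also arose in a split that mixed control and Rb1 samples. Every such split keeps 2 samples of a group on the same side, so it carries part of any group difference. The values of the other splits therefore do not show what chance alone would give.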
